A study of Mus musculus with 6 samples.

How the data were processed

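The values used here are the submitters' log2 RMA values of 45037 probe sets in 6 arrays, made from RNA extracted with TRIzol. Their notes name RMA and give no version. The deposited table of comparisons gives, per the file headers, a q-value for each probe set, which the authors made by a test and a method that are not given in the sources used here. Nothing was normalized again in the main analysis. Of the probe sets 34945 carried a single gene symbol, 932 several and 9160 none. Symbols were brought up to date through the Entrez ID in a RefSeq annotation, which matched 34741 probe sets. Each of 18193 genes was read from the probe set with the highest mean over the 6 arrays among those with a single symbol.

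Transgenic and wild-type lungs were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A size filter asked for a log2 difference of at least 1. The SE is the moderated one of limma. Where 1 transgenic array is left out, the remaining one is assumed to vary like the wild-type arrays. Of 44 gene lists written from general knowledge 42 had at least 5 measured genes and were tested with camera at a correlation of 0.01 between genes, adjusted over the 42 lists. The test was repeated with an estimated correlation, with 0.05, and with fry, which asks whether the genes of a list move on balance in 1 direction. With an estimated correlation camera also draws its p-values from the 4 residual degrees of freedom. Other alternatives were filters on low values, quantile normalization again, centring of arrays, an intensity trend, robust moderation, no moderation, array weights, other ways to read a gene from its probe sets, the replicate number as a block, and leaving out each array. Under the block, wild-type replicates 3 and 4 have no transgenic partner. That setting therefore compares the transgenic arrays with wild-type replicates 1 and 2 only and has fewer residual degrees of freedom. Leaving out both wild-type replicates 2 and 4 was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

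The groups, the tests, the lists, the alternatives other than those named as added, and the rule for naming genes were chosen before the data were examined. That rule takes Il13 and Scgb1a1, the 12 largest rises and 12 largest falls among genes past the threshold whose transgenic values both lie outside the wild-type range, passing over clone names, and up to 4 members of each list with the largest changes past the threshold, or the largest change where none passed. Genes outside it are stated to be chosen after their values were seen. In simulated data of the same size with 200 changed genes, the pipeline recovered 20% of genes changed by 0.58 on the log2 scale, 82% at 1, 98% at 2 and 100% at 4, and 5.66% of its 159 calls were unchanged genes. Of 41 simulated lists it called the shifted one and 0 of the others. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.64 (ciliated cell markers). False list calls due to correlated genes could therefore not show. The simulation also held far fewer changed genes than the 3448 called in the data. The 6 columns of single arrays in the authors' table of fold changes were not used, because their names match no sample label.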

Results

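Lung RNA of mice that express IL13 in the airway on demand was profiled on Affymetrix whole-genome mouse arrays. In the transgenic line the promoter of the club cell gene CC10 (Scgb1a1) drives a doxycycline-dependent activator, which in turn switches on IL13, a type 2 cytokine of allergic airway disease. Animals of 6 to 10 weeks on the C57BL/6 background drank doxycycline at 2 mg/mL for 7 days, transgenic and wild-type alike, and the left upper lobe was taken. The series holds 2 IL13-transgenic and 4 wild-type samples, each on its own array, and the labels call them biological replicates, so p-values describe the spread among these animals. RMA log2 values ran from 2.297 to 15.19, and the median of an array lay between 5.28 and 5.31. Precision is limited by the number of arrays.

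The only comparison the design implies asks what 7 days of IL13 in the airway change in lung gene expression. Single genes of macrophage proteases, chitinase-like proteins and chemokines rose steeply in transgenic lungs, and single genes of club cells, endothelium, alveolar type I cells and xenobiotic metabolism fell. As lists, chitinases (adjusted p = 0.11 with an estimated correlation), CC and CXC chemokines (0.10 and 0.12), club cell (0.23), endothelial (0.16), alveolar type I (0.15) and xenobiotic genes (0.10) were called at the preset correlation and not at the estimated one. The ribonuclease gene Rnase2a rose at least 229-fold (log2 difference 7.84 ± 0.23, SE, n = 2 and 4) from a wild-type mean of 3.798 near the floor of the array, the macrophage elastase gene Mmp12 141-fold (7.14 ± 0.38) and the arginase gene Arg1 129-fold (7.01 ± 0.24). Bpifa1, which encodes a secreted protein of the upper airways, fell by 5.85 on the log2 scale (SE 0.47), or 57.5-fold. Values of 13 or more may be compressed, so changes of genes at such levels may be too small. Here these are Mmp12 (13.37) and Arg1 (13.24) in transgenic and Bpifa1 (13.54) in wild-type lungs. Of 18193 genes, 1534 were higher and 1914 lower at an adjusted p under 0.05 in limma, and with a change of at least 2-fold 549 were higher and 347 lower. Changes of at least 16-fold were almost all rises, with 20 genes higher and 3 lower. Leaving out transgenic replicate 1 gave 731 higher and 580 lower genes, and leaving out transgenic replicate 2 gave 902 and 860. Without wild-type replicate 1 the count of lower genes was 1245.

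The genotypes separated along principal component 1, which held 68.1% of the variance. Across genes, which are not independent replicates, Pearson's r was 0.987 to 0.994 between arrays of a genotype and 0.967 to 0.973 between genotypes. For 7578 genes (41.7%) both transgenic values lay above, or both below, all wild-type values, where chance gives 13.3%. An exact permutation test of a single gene over the 15 splits of 6 arrays into 2 and 4 cannot go below p = 0.133 (two-sided, the smaller one-sided value doubled), so calls rest on the variance that limma shares across genes. Wild-type replicate 2 was high for several goblet cell genes and wild-type replicate 4 had the highest means of heart and fat genes, and without both of them 1291 genes were higher and 1677 lower.

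Il13 itself read near the floor of the array. Its probe set gave log2 values of 4.24 and 4.09 in the transgenic arrays and 3.84, 3.72, 4.03 and 3.79 in the wild-type arrays, a difference of 0.32 ± 0.12 that did not pass (adjusted p = 0.11, limma). Where this probe set lies relative to the transgene's coding sequence is not given in the sources used here, and a probe outside it would check nothing about the labels. Scgb1a1, the gene whose promoter drives the transgene, was among the brightest on the array at 14.84 in transgenic and 15.03 in wild-type lungs (difference -0.19 ± 0.14, adjusted p = 0.40). The brightest values of the arrays were 15.10 to 15.19, so its probe set was near saturation and a change would be compressed.

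After Rnase2a, Mmp12 and Arg1 the largest rises were those of 9 further genes. Chil4, a chitinase-like protein, rose 115-fold (log2 difference 6.85 ± 0.33) and Slc26a4, the anion exchanger pendrin, 76.9-fold (6.27 ± 0.42). The acute-phase gene Saa3 rose 49.5-fold (5.63 ± 0.41), the gluconeogenic enzyme gene Fbp1 49.2-fold (5.62 ± 0.28) and the ribonuclease gene Rnase2b at least 39.5-fold (5.304 ± 0.20), from a wild-type mean of 3.71 near the floor. Fxyd4, a regulator of the sodium pump, rose by 5.19 ± 0.18 on the log2 scale, the cysteine protease gene Ctsk by 4.90 ± 0.17, Wfdc17 by 4.89 ± 0.17 and the serine protease gene Corin by 4.77 ± 0.36, a lower bound from a wild-type mean of 4.47 near the floor. Each of these 12 genes passed with an adjusted p of 8.2e-05 or less. Rnase2a and Rnase2b, and Chil4 and its relatives, belong to families of similar sequence, whose members an array may not fully separate.

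**Figure D1:**
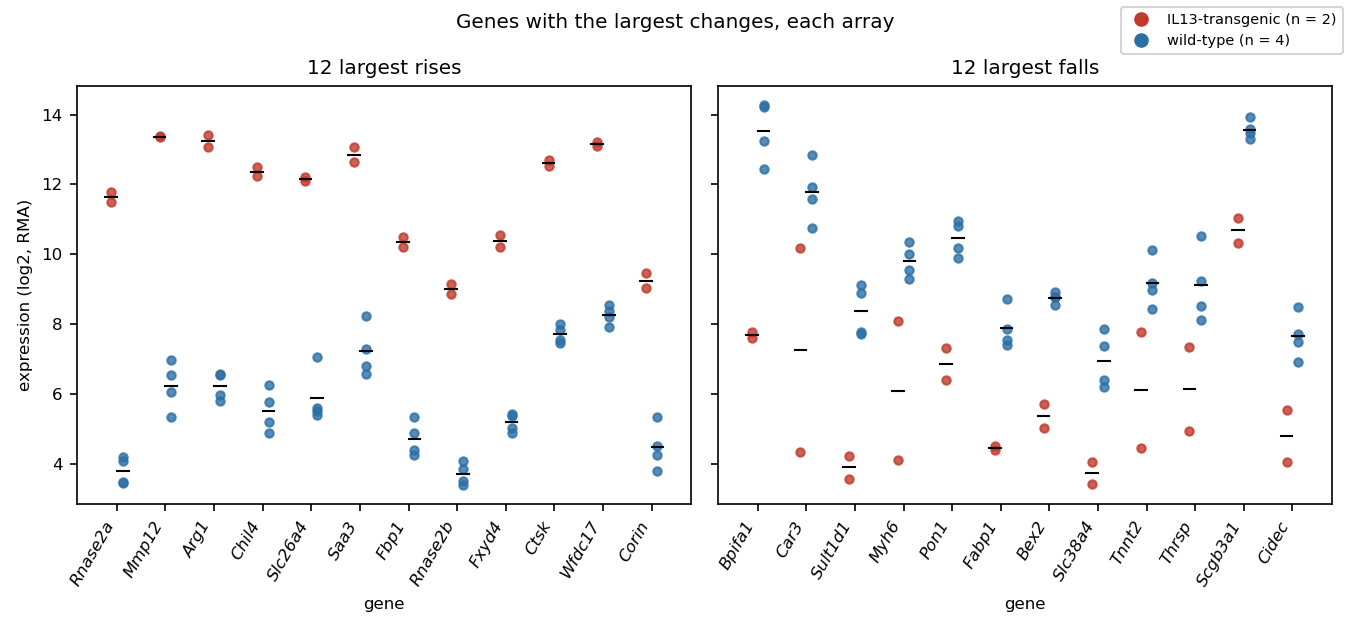
Expression (log2 RMA value, vertical axis) of the 12 genes with the largest rise and the 12 with the largest fall, each point an array (2 IL13-transgenic, 4 wild-type) and each bar a group mean. The transgenic points of Car3, Myh6, Tnnt2 and Thrsp lie far apart, whereas those of the 12 risen genes lie close together and well above all wild-type points.

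After Bpifa1, the sulfotransferase gene Sult1d1 fell at least 22.3-fold (log2 difference -4.48 ± 0.41) and the paraoxonase gene Pon1 12-fold (-3.59 ± 0.34). The fatty acid binding protein gene Fabp1 fell by 3.44 on the log2 scale (SE 0.32), Bex2 by 3.39 (SE 0.19), the amino acid transporter gene Slc38a4 by 3.22 (SE 0.44), and the secretoglobin gene Scgb3a1 by 2.88 (SE 0.23). The transgenic means of Sult1d1 (3.90), Slc38a4 (3.74) and Fabp1 (4.44) lay near the floor, so their falls are lower bounds. The other 5 belong to muscle or fat, namely Car3 (-4.52 ± 1.33), Myh6 (-3.71 ± 0.89), Tnnt2 (-3.07 ± 0.80), Thrsp (-2.96 ± 0.75) and Cidec (-2.85 ± 0.47). With each probe set tested on its own, 1 of 4 passed as lower for Car3, 1 of 2 for Myh6, and 2 of 3 for Tnnt2 and for Thrsp. Without transgenic replicate 2 the differences of Car3, Myh6, Tnnt2 and Thrsp shrank to -1.60, -1.72, -1.41 and -1.76, and without transgenic replicate 1 those of Car3, Myh6 and Tnnt2 grew to -7.45, -5.70 and -4.73, which are lower bounds in size, as transgenic replicate 2 read near the floor (4.33, 4.10 and 4.45). Calls ended for Car3 (adjusted p = 0.19), Tnnt2 (0.15) and Thrsp (0.22) without transgenic replicate 2, and for Car3 (0.092), Myh6 (0.056), Tnnt2 (0.068) and Thrsp (0.067) without wild-type replicate 1. Leaving out wild-type replicate 3 or 4 also ended the calls of Car3 (0.093 and 0.080) and Tnnt2 (0.059 and 0.0504).

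Gene lists fixed before the data were examined were tested with limma's camera, 42 of the 44 being large enough. At the preset correlation of 0.01 between genes, 21 lists were higher and 10 lower in transgenic lungs. With the correlation estimated from the data 3 higher lists held, namely lysosome genes (adjusted p = 0.016), alternatively activated macrophage genes (0.037) and matrix metalloproteinases and cathepsins (0.037), and none of the lower lists did. This setting also has few degrees of freedom, so a lost call is not by itself a sign of correlated genes. Alveolar type II markers had an estimated correlation of -0.031, below the preset one, yet their camera adjusted p rose from 3.3e-05 to 0.089. The smaller of a list's counts of risen and fallen genes, mostly 0 to 3, changed by 1 or 2 genes for many lists when 1 array was left out. Every other called list is therefore given with its adjusted p under an estimated correlation.

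**Figure D2:**
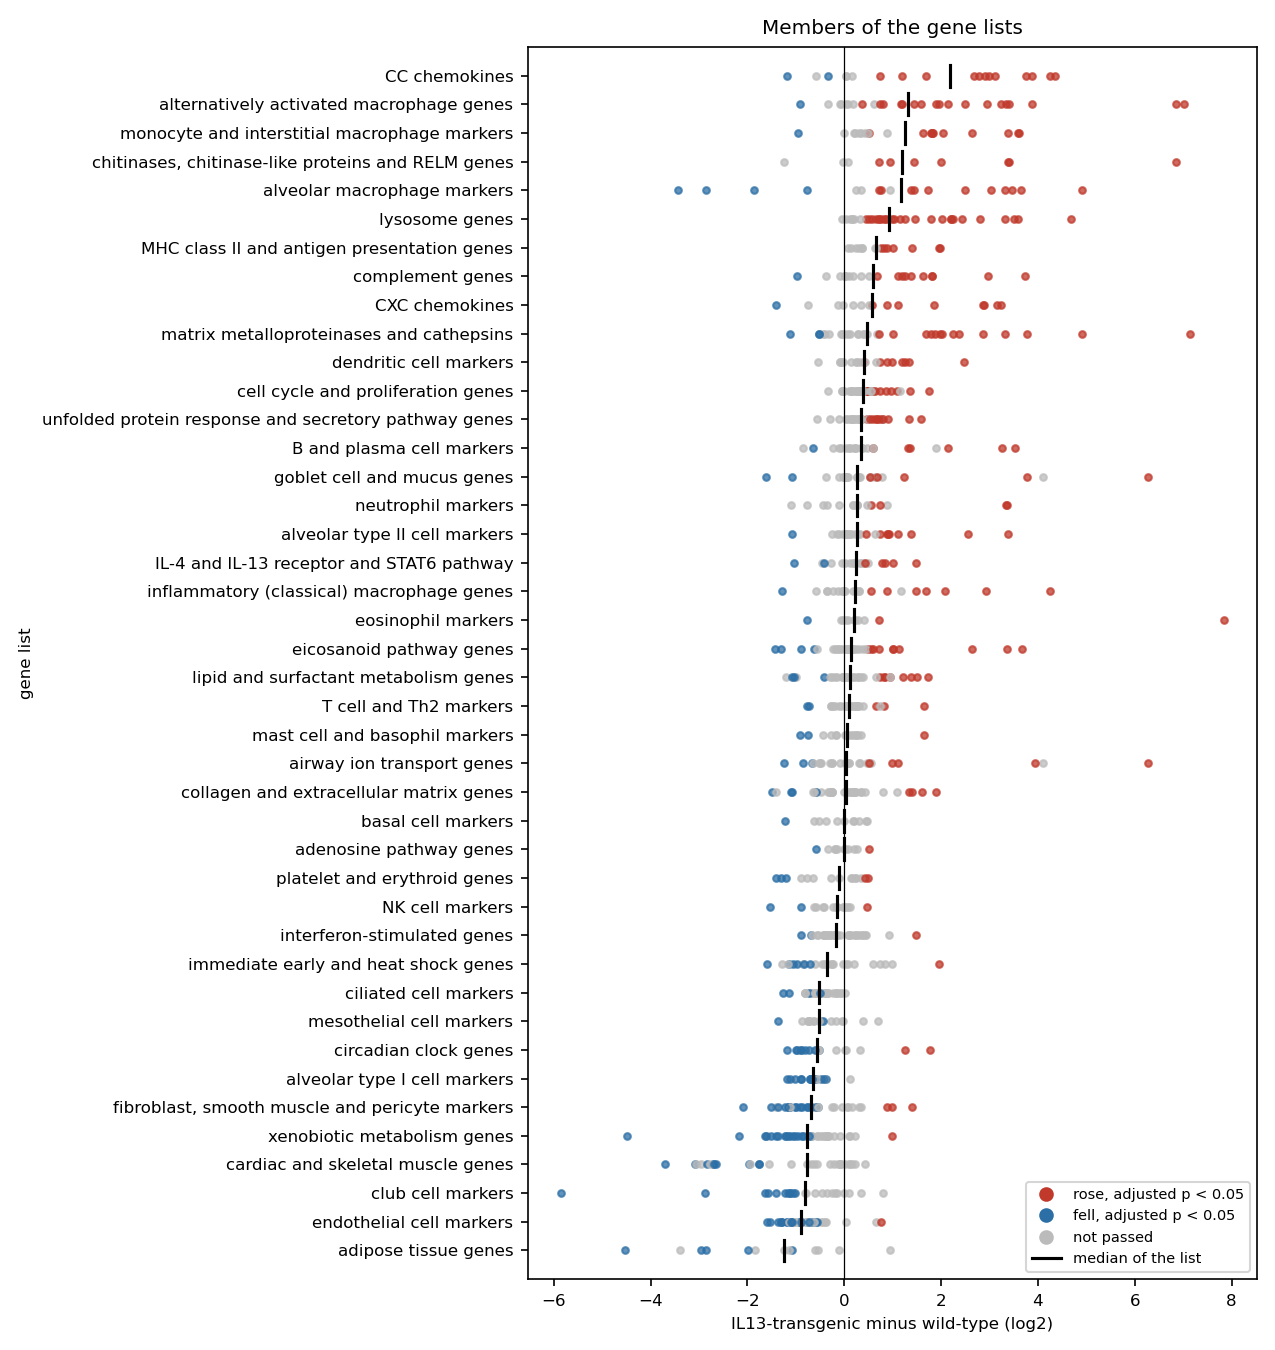
Difference between IL13-transgenic and wild-type lungs (log2, horizontal axis) of each measured member of the 42 tested gene lists, ordered by their median (black bar). Red points rose, blue points fell and grey points did not pass at an adjusted p of 0.05. CC chemokines have the highest median, 2.18, and adipose tissue genes the lowest, -1.24.

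Most genes of alternatively activated macrophages, the state that IL-4 and IL-13 induce in culture, rose. Of 26 measured genes 18 rose, 1 fell and 7 did not pass (19 and 1 adjusted over the list alone), with a median log2 difference of 1.32. Arg1 and Chil4 led, followed by the chemokine gene Ccl24 (3.88 ± 0.18) and Retnla, which encodes a resistin-like molecule (3.40 ± 0.82, a lower bound, since its transgenic values of 14.77 and 14.78 were near saturation). Of the list of matrix metalloproteinases and cathepsins 14 of 31 rose, 3 fell and 14 did not pass (15 and 3 adjusted over the list alone), and 1 fell without either transgenic replicate. Beside Mmp12 and Ctsk, Mmp19 rose by 3.78 ± 0.16 and the collagenase gene Mmp13 by 3.32 ± 0.16, lower bounds from wild-type means near the floor (3.73 and 3.21). Lysosome genes had the largest share of risen genes among the 42 lists, with 25 of 32 higher, 0 lower and 7 not passed (26 and 0 adjusted over the list alone). In it Gpnmb, a glycoprotein of macrophages that engulf debris, rose by 4.68 ± 0.14, Cd68 by 3.59 ± 0.15 and the galactosidase gene Gla by 3.50 ± 0.11. Retnla was 13.73 in wild-type replicate 2 and 10.46 to 10.67 in the other wild-type arrays, and its call ended without transgenic replicate 1 (adjusted p = 0.14) or 2 (0.12) and without wild-type replicate 1 (0.058) or 3 (0.055).

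Many markers of macrophages and monocytes rose. For alveolar macrophage markers 11 of 18 rose, 4 fell and 3 did not pass (11 and 4 adjusted over the list alone, list adjusted p = 1.7e-06, and adjusted p = 0.10 with an estimated correlation). The scavenger receptor gene Marco rose by 3.66 ± 0.20 and the integrin gene Itgax by 3.46 ± 0.13, whereas Fabp1 and Cidec, which resident alveolar macrophages also express, fell. The surface lectin gene Siglecf, on this list and on that of eosinophils, fell by 0.77 (SE 0.21), but by 0.46 without transgenic replicate 2. Cidec is also on the adipose list and ranked all 6 arrays in the same order as that list's mean, so its fall cannot be assigned to macrophages. Of 20 monocyte and interstitial macrophage markers 11 rose, 1 fell and 8 did not pass (15 and 1 adjusted over the list alone, list adjusted p = 3.0e-10, and adjusted p = 0.10 with an estimated correlation), among them Ms4a7 (3.61 ± 0.12) and the lipid receptor gene Trem2 (3.37 ± 0.15). Of 22 genes of classical inflammatory macrophages 7 rose, 1 fell and 14 did not pass (7 and 1 adjusted over the list alone, list adjusted p = 0.0091, and adjusted p = 0.22 with an estimated correlation). This call ended at a correlation of 0.05 (adjusted p = 0.056), and among genes at or above the median expression the direction turned (median -0.29, adjusted p = 0.81). The chemokine gene Ccl3 rose by 4.24 ± 0.32, the cytokine gene Il6 by 2.94 ± 0.29 and Acod1, the itaconate synthase, by 2.09 ± 0.13, lower bounds from wild-type means near the floor (3.83, 3.18 and 4.08). Without transgenic replicate 1 the count of 7 was 4.

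Many chemokine genes rose. Of 18 CC chemokines 12 rose, 2 fell and 4 did not pass (12 and 2 adjusted over the list alone, list adjusted p = 6.8e-08, and adjusted p = 0.10 with an estimated correlation), and the 2 falls were 0 without transgenic replicate 1 and 1 without each of the other arrays. Ccl9 rose 20.5-fold (log2 difference 4.36 ± 0.13), the eosinophil attractant gene Ccl24 14.7-fold (3.88 ± 0.18) and the monocyte attractant gene Ccl8 13.4-fold (3.75 ± 0.49). Of 15 CXC chemokines 8 rose, 1 fell and 6 did not pass (8 and 2 adjusted over the list alone, list adjusted p = 5.4e-05, and adjusted p = 0.12 with an estimated correlation). The neutrophil attractant genes Cxcl3 and Cxcl5 rose by 3.25 ± 0.21 and 3.16 ± 0.16, lower bounds from wild-type means near the floor (2.81 and 3.08).

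Chitinase and RELM genes encode secreted proteins of epithelium and macrophages. Of 10 measured genes 7 rose, 0 fell and 3 did not pass (7 and 0 adjusted over the list alone, list adjusted p = 7.7e-06, and adjusted p = 0.11 with an estimated correlation). Chia1, an acidic chitinase, rose 10.4-fold (3.38 ± 0.15). Goblet cell and mucus genes moved both ways, with 5 of 24 higher, 2 lower and 17 not passed (6 and 2 adjusted over the list alone, list adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). This call also ended among genes at or above the median expression (adjusted p = 0.22), among genes with a log2 value of at least 6 in 2 or more arrays (0.10), at a correlation of 0.05 (0.081) and in fry (0.068). Slc26a4 led this list and Pigr, the receptor that carries IgA across epithelium, rose by 3.77 ± 0.50, whereas the trefoil peptide gene Tff2 fell by 1.61 (SE 0.45). The count of 5 was 2 without transgenic replicate 1, 3 without transgenic replicate 2 or wild-type replicate 3, and 8 without wild-type replicate 2. The call of Tff2 ended without transgenic replicate 1 (adjusted p = 0.19) or 2 (0.16) and without wild-type replicate 1 (0.060).

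Clca1 and Muc5ac, goblet cell genes that are named here after their values were seen, did not pass. Clca1 was 10.98 and 11.81 in the transgenic arrays, and 4.49, 11.44, 5.90 and 7.37 in wild-type replicates 1 to 4, a difference of 4.10 ± 1.57 (adjusted p = 0.11). Without wild-type replicate 2 the difference was 5.48 and passed (adjusted p = 0.0016). The gel-forming mucin gene Muc5ac differed by 0.03 ± 0.30 (adjusted p = 0.96).

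**Figure D3:**
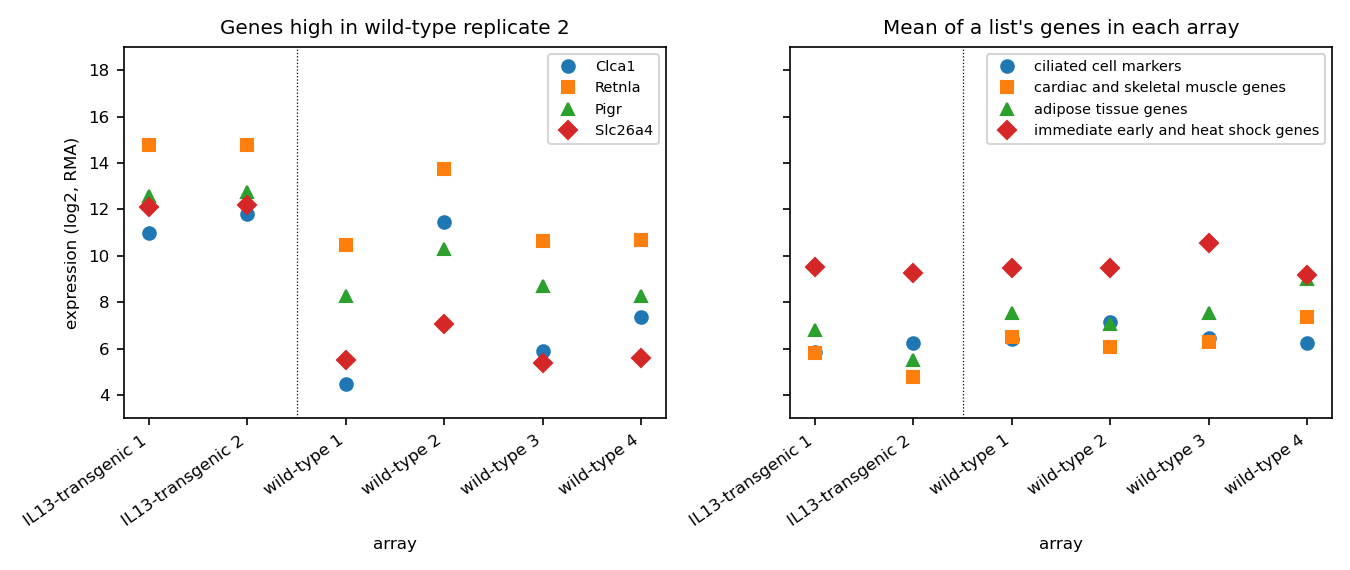
Expression (log2 RMA value, vertical axis) in each of the 6 arrays of Clca1, Retnla, Pigr and Slc26a4, left, and of the mean over the genes of 4 lists, right. Wild-type replicate 2 reaches 11.44 for Clca1, and wild-type replicate 4 has the highest means of cardiac (7.35) and adipose genes (8.99).

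Genes of the IL-4 and IL-13 receptor and STAT6 pathway changed in part. Of 19 measured genes 5 rose, 2 fell and 12 did not pass (6 and 3 adjusted over the list alone, list adjusted p = 0.029, and adjusted p = 0.15 with an estimated correlation). This call also ended under both filters on low values (adjusted p = 0.12 and 0.075) and at a correlation of 0.05 (0.095). The feedback inhibitor gene Socs3 rose by 1.48 ± 0.27 and the receptor gene Il13ra1 by 1.01 ± 0.14, and Irs1, an adaptor of insulin and IL-4 receptors, fell by 1.03 (SE 0.16). Without transgenic replicate 1 only 1 gene of the list rose and 0 fell, the list's adjusted p was 0.056, and the calls of Socs3 (adjusted p = 0.082) and Irs1 (0.054) ended.

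Genes of secretion and of cell division rose in part. Unfolded protein response and secretory pathway genes had 11 of 31 higher, 0 lower and 20 not passed (18 and 1 adjusted over the list alone, list adjusted p = 4.2e-07, and adjusted p = 0.10 with an estimated correlation). Sdf2l1, a partner of endoplasmic reticulum chaperones, rose by 1.59 ± 0.14 and Edem1, which sorts misfolded glycoproteins for degradation, by 1.34 ± 0.13. The count of 11 was 6 without transgenic replicate 1 and 4 without transgenic replicate 2. Cell cycle and proliferation genes had 13 of 44 higher, 0 lower and 31 not passed (15 and 0 adjusted over the list alone, list adjusted p = 3.2e-07, and adjusted p = 0.15 with an estimated correlation). Cdk1, the mitotic kinase, rose by 1.74 ± 0.27 and the proliferation marker gene Mki67 by 1.35 ± 0.22. Here the count of 13 was 2 without transgenic replicate 1, 5 without transgenic replicate 2 and 7 without wild-type replicate 1 or 3, and without transgenic replicate 1 the adjusted p of Cdk1 and of Mki67 was 0.0504.

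Complement, eicosanoid and antigen presentation genes rose in part. Of 20 complement genes 10 rose, 1 fell and 9 did not pass (11 and 1 adjusted over the list alone, list adjusted p = 6.8e-06, and adjusted p = 0.19 with an estimated correlation), led by the complement protease gene Cfi (3.73 ± 0.20) and the anaphylatoxin receptor gene C3ar1 (2.97 ± 0.12). Eicosanoid pathway genes had 10 of 34 higher, 4 lower and 20 not passed (10 and 4 adjusted over the list alone, list adjusted p = 0.0066, adjusted p = 0.10 with an estimated correlation, and 0.066 at a correlation of 0.05). The prostacyclin receptor gene Ptgir rose by 3.68 ± 0.17 and the phospholipase gene Pla2g7 by 3.37 ± 0.13, and Hpgd, which breaks down prostaglandins, fell by 1.43 (SE 0.16). In this list 6 genes rose without transgenic replicate 1 and 2 fell without transgenic replicate 2. MHC class II and antigen presentation genes had 7 of 15 higher, 0 lower and 8 not passed (10 and 0 adjusted over the list alone, list adjusted p = 7.1e-07, and adjusted p = 0.10 with an estimated correlation), led by the lysosomal proteases Ctss (1.98 ± 0.12) and Lgmn (1.96 ± 0.13). Their count of 7 was 3 without transgenic replicate 1 and 11 without wild-type replicate 2.

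Lists of granulocytes rested on few genes. Of 11 eosinophil markers 2 rose, 1 fell and 8 did not pass (3 and 1 adjusted over the list alone, list adjusted p = 0.046, and adjusted p = 0.19 with an estimated correlation). The risen genes were Rnase2a and Ear3 (0.72 ± 0.22), ribonucleases that macrophages can also express, and the surface lectin gene Siglecf fell by 0.77 (SE 0.21). Epx, the eosinophil peroxidase gene, named after its values were seen, stayed near the floor at 3.33 and 3.13 (difference 0.20 ± 0.12, adjusted p = 0.30). The list's adjusted p was 0.18 without transgenic replicate 1, 0.054 without wild-type replicate 4, 0.079 after quantile normalization again, 0.073 with the replicate number as a block and 0.095 at a correlation of 0.05, and 1 gene rose without transgenic replicate 1 or wild-type replicate 1, 2 or 3. Siglecf was no longer called without transgenic replicate 2 (difference -0.46, adjusted p = 0.25) or wild-type replicate 1 (0.062), 3 (0.078) or 4 (0.051), nor Ear3 without transgenic replicate 1 (0.27) or 2 (0.13) or wild-type replicate 1 (0.098), 2 (0.073) or 3 (0.11). Of 16 neutrophil markers 4 rose, 0 fell and 12 did not pass (4 and 0 adjusted over the list alone, list adjusted p = 0.022, and adjusted p = 0.23 with an estimated correlation). This call also ended under both filters on low values (adjusted p = 0.057 and 0.067) and at a correlation of 0.05 (0.074). Wfdc21 rose by 3.37 ± 0.20 and the iron-chelating lipocalin gene Lcn2, which epithelium also makes, by 3.35 ± 0.29. Without either transgenic replicate the count of 4 was 2.

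Markers of B cells and of dendritic cells rose in part. Of 23 B and plasma cell markers 6 rose, 1 fell and 16 did not pass (8 and 1 adjusted over the list alone, list adjusted p = 8.1e-04, and adjusted p = 0.10 with an estimated correlation), led by the low-affinity IgE receptor gene Fcer2a (3.53 ± 0.13) and the IgM heavy chain gene Ighm (3.26 ± 0.47). Of 19 dendritic cell markers 8 rose, 0 fell and 11 did not pass (9 and 1 adjusted over the list alone, list adjusted p = 2.9e-04, and adjusted p = 0.12 with an estimated correlation). The transcription factor gene Batf3 rose by 2.48 ± 0.19 and the actin-bundling gene Fscn1 by 1.33 ± 0.35. The count of 8 was 2 without transgenic replicate 1 and 5 without transgenic replicate 2, and the call of Fscn1 ended without either (adjusted p = 0.14 and 0.16). T cell and Th2 markers did not pass as a list (adjusted p = 0.12, and 0.45 with an estimated correlation), with 3 of 29 higher, 2 lower and 24 not passed (3 and 2 adjusted over the list alone). The cytokine receptor gene Il7r rose by 1.64 ± 0.11, the costimulatory receptor gene Icos by 0.81 ± 0.21, and the transcription factor gene Rora fell by 0.77 (SE 0.12). This list passed without transgenic replicate 2 (adjusted p = 0.047) and without wild-type replicate 2 (0.044), 1 of its genes rose without transgenic replicate 1, and 1 fell without transgenic replicate 1 or 2 or wild-type replicate 3 or 4. Icos lost its call without transgenic replicate 1 (adjusted p = 0.21) or 2 (0.10) and without wild-type replicate 1 (0.068), 3 (0.072) or 4 (0.054).

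Natural killer, mast and blood cell lists did not pass. NK cell markers had 1 of 16 higher, 2 lower and 13 not passed (1 and 2 adjusted over the list alone, list adjusted p = 0.19, 0.55 with an estimated correlation, and 0.035 with the replicate number as a block), with falls in the receptor gene Klra8 (-1.54 ± 0.43, a lower bound in size at a transgenic mean of 4.05) and the granzyme gene Gzma (-0.90 ± 0.16). Mast cell and basophil markers had 1 of 17 higher, 2 lower and 14 not passed (1 and 2 adjusted over the list alone, list adjusted p = 0.57, and 0.75 with an estimated correlation). The histidine decarboxylase gene Hdc rose by 1.65 ± 0.21 and the transcription factor gene Gata2 fell by 0.91 (SE 0.26). Platelet and erythroid genes had 2 of 15 higher, 3 lower and 10 not passed (2 and 4 adjusted over the list alone, list adjusted p = 0.68, and 0.88 with an estimated correlation), with falls in the platelet chemokine gene Ppbp (-1.42 ± 0.42) and the haem synthesis gene Alas2 (-1.31 ± 0.28). Without transgenic replicate 1 the calls of Klra8 (adjusted p = 0.26), Gzma (0.070), Gata2 (0.31, difference -0.41), Ppbp (0.36, difference -0.86) and Alas2 (0.12) ended, and 0 genes fell in each of these lists. Gata2 was at -1.41 without transgenic replicate 2. Of the platelet and erythroid genes 0 rose without transgenic replicate 1 or wild-type replicate 1, and 1 without transgenic replicate 2. Without transgenic replicate 2 the calls of Klra8 (0.10) and Alas2 (0.068) ended and 1 NK and 1 mast cell gene fell, without wild-type replicate 1 those of Gata2 (0.094) and Ppbp (0.11), with 0 mast cell and 1 platelet gene lower, without wild-type replicate 2 those of Gata2 (0.067) and Ppbp (0.061), and without wild-type replicate 3 those of Klra8 (0.079) and Gata2 (0.095).

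Among airway epithelial markers, many club cell genes and few ciliated and basal cell genes fell. Of 23 club cell markers 0 rose, 11 fell and 12 did not pass (0 and 12 adjusted over the list alone, list adjusted p = 6.6e-06, and adjusted p = 0.23 with an estimated correlation), with a median log2 difference of -0.82. Beside Bpifa1 and Scgb3a1 the secretoglobin gene Scgb3a2 fell by 1.58 (SE 0.18), while Scgb1a1, near saturation, cannot be read. The wild-type means of Scgb3a1 (13.57) and Scgb3a2 (14.16) were also high, so their falls may be compressed. Of 36 ciliated cell markers 0 rose, 4 fell and 32 did not pass (0 and 3 adjusted over the list alone, list adjusted p = 3.5e-05, adjusted p = 0.48 with an estimated correlation, and 0.19 in fry), with falls in Mlf1 (-1.26 ± 0.19) and the tubulin-binding gene Tppp3 (-1.14 ± 0.11). Far more ciliated markers fell with the replicate number as a block, where wild-type replicates 1 and 2 were the only controls compared. Without transgenic replicate 1 the club count of 11 was 7 and the ciliated count of 4 was 2. Mean ciliated expression was 7.14 in wild-type replicate 2 and 6.24 to 6.47 in the other wild-type arrays, against 5.87 and 6.25 in the transgenic arrays, so the genotypes overlapped. Basal cell markers did not pass, with 0 of 11 higher, 1 lower, Snai2 (-1.23 ± 0.15), and 10 not passed (0 and 1 adjusted over the list alone, list adjusted p = 0.90, and 0.92 with an estimated correlation), and their median (0.00387) and mean (-0.12) differed in sign. Without transgenic replicate 1, 2 basal genes fell, and the direction of this list turned without transgenic replicate 2 (median 0.10) and without wild-type replicate 3 (-0.06 by the median, higher by the test).

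Many xenobiotic metabolism genes, among them club cell enzymes, fell. Of 36 measured genes 1 rose, 18 fell and 17 did not pass (1 and 26 adjusted over the list alone, list adjusted p = 3.8e-09, and adjusted p = 0.10 with an estimated correlation). Sult1d1 led, and the cytochrome P450 gene Cyp2e1 fell by 2.17 (SE 0.56), although it ranked all 6 arrays in the same order as the mean of adipose tissue genes. The count of 18 was 9 without transgenic replicate 1. Without transgenic replicate 2 the difference of Cyp2e1 was -1.21 (adjusted p = 0.22), and its call also ended without wild-type replicate 1 (0.066) or 3 (0.060).

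Markers of the alveolar wall parted. Of 20 alveolar type I cell markers 0 rose, 16 fell and 4 did not pass (0 and 19 adjusted over the list alone, list adjusted p = 1.8e-09, and adjusted p = 0.15 with an estimated correlation), with Igfbp2 at -1.19 ± 0.17 and the protease inhibitor gene Timp3 at -1.13 ± 0.21. Of 36 endothelial cell markers 1 rose, 21 fell and 14 did not pass (2 and 25 adjusted over the list alone, list adjusted p = 6.7e-10, and adjusted p = 0.16 with an estimated correlation), and their median difference was -0.90. The endothelin receptor gene Ednrb fell by 1.60 (SE 0.20, with 1 of its 3 probe sets past the threshold), Lyve1, of lymphatic and some other endothelium, by 1.38 (SE 0.23) and the angiopoietin receptor gene Tek by 1.31 (SE 0.16). Of alveolar type II cell markers more rose than fell, with 9 of 24 higher, 1 lower and 14 not passed (11 and 1 adjusted over the list alone, list adjusted p = 3.3e-05, and adjusted p = 0.089 with an estimated correlation). Chia1 and the alarmin gene Il33 (2.55 ± 0.16) led, and the surfactant gene Sftpc, named after its values were seen, differed by 0.02 ± 0.10 (adjusted p = 0.90) at 15.15 and 15.12, near saturation. Without transgenic replicate 1 the count of fallen type I markers was 6 and that of endothelial markers 7, without transgenic replicate 2 the type I count was 10, and Timp3 lost its call without transgenic replicate 1 (adjusted p = 0.094).

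Many stromal markers and few pleural markers fell. Of 35 fibroblast, smooth muscle and pericyte markers 3 rose, 18 fell and 14 did not pass (3 and 18 adjusted over the list alone, list adjusted p = 7.7e-06, and adjusted p = 0.16 with an estimated correlation). The smooth muscle gene Cnn1 fell by 2.09 (SE 0.33) and the integrin gene Itga8 by 1.51 (SE 0.14), and the collagen gene Col3a1 rose by 1.40 ± 0.36. The count of 18 was 9 without transgenic replicate 1. Of 17 mesothelial cell markers 0 rose, 2 fell and 15 did not pass (0 and 0 adjusted over the list alone, list adjusted p = 0.019, and adjusted p = 0.55 with an estimated correlation), the fallen genes being Cpe (-1.36 ± 0.33) and the keratin gene Krt18 (-0.45 ± 0.12). This list's adjusted p was 0.48 without transgenic replicate 2, 0.066 without wild-type replicate 4, 0.076 and 0.059 under the filters on low values, 0.090 with the replicate number as a block, 0.069 at a correlation of 0.05 and 0.28 in fry. Its mean was 9.45 in transgenic replicate 1, above wild-type replicates 1 (9.41) and 2 (9.10), and 0 of its genes fell without transgenic replicate 2 or wild-type replicate 1 or 3, and 1 without transgenic replicate 1. Collagen and extracellular matrix genes went both ways, with 4 of 34 higher, 4 lower and 26 not passed (5 and 5 adjusted over the list alone, list adjusted p = 0.92, and 0.97 with an estimated correlation). Fibronectin (Fn1, 1.89 ± 0.13), Tgfb1 (1.61 ± 0.12) and Col3a1 rose and Col12a1 fell (-1.49 ± 0.18), although another probe set of Col12a1 passed in the opposite direction. The median of the matrix list was 0.03 while the test leaned lower, and it leaned higher without transgenic replicate 2 (median 0.18) or wild-type replicate 3 (0.08) or 4 (0.15), and 2 genes rose without either transgenic replicate. Col3a1 lost its call without transgenic replicate 1 (adjusted p = 0.20) or 2 (0.11) and without wild-type replicate 1 (0.068), Cpe without transgenic replicate 2 (-0.80, adjusted p = 0.18) or wild-type replicate 1 (0.056) or 3 (0.051), and Krt18 without any 1 array other than wild-type replicate 4 (adjusted p = 0.061 to 0.25).

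Some genes of heart and fat, tissues next to the lung lobes, fell in transgenic lungs, and the lists varied widely within each genotype. Of 31 cardiac and skeletal muscle genes 0 rose, 9 fell and 22 did not pass (0 and 12 adjusted over the list alone, list adjusted p = 2.9e-04, adjusted p = 0.45 with an estimated correlation, and 0.12 in fry), with the cardiac myosin gene Myh6 and the troponin gene Tnnt2 in the lead. The mean of the list was 5.82 and 4.78 in the transgenic arrays and 6.51, 6.06, 6.30 and 7.35 in wild-type replicates 1 to 4. Of 13 adipose tissue genes 0 rose, 5 fell and 8 did not pass (0 and 6 adjusted over the list alone, list adjusted p = 0.0019, adjusted p = 0.39 with an estimated correlation, 0.096 in fry, and 0.073 and 0.055 under the filters on low values), with means of 6.78 and 5.50 against 7.55, 7.05, 7.54 and 8.99. The carbonic anhydrase gene Car3 and the lipogenic gene Thrsp led. The cardiac count of 9 was 3 without transgenic replicate 2 or wild-type replicate 1, 4 without wild-type replicate 3 and 14 without wild-type replicate 2, and the adipose count of 5 was 2 without transgenic replicate 2 or wild-type replicate 1 and 3 without wild-type replicate 3. With an intensity trend and robust moderation 3 cardiac and 2 adipose genes fell. The limits of Myh6, Tnnt2, Car3 and Thrsp given among the largest falls hold here.

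Lipid, ion transport, adenosine and interferon genes did not pass as lists. Lipid and surfactant metabolism genes had 8 of 32 higher, 3 lower and 21 not passed (8 and 4 adjusted over the list alone, list adjusted p = 0.0501, and 0.55 with an estimated correlation), with rises in the nuclear receptor gene Pparg (1.73 ± 0.15) and the lipid droplet gene Plin2 (1.51 ± 0.14). That list passed under both filters on low values (adjusted p = 0.0060 and 0.015), after centring of the arrays (0.044), with an intensity trend (0.044, robust 0.040), with the mean of probe sets (0.014) or the most variable one (0.0058), with the replicate number as a block (0.0020), and without wild-type replicate 3 (0.010) or 4 (0.024), and its 8 rises were 4 without transgenic replicate 1 and 5 without transgenic replicate 2, and its 3 falls were 1 without either. Airway ion transport genes had 5 of 26 higher, 3 lower and 18 not passed (6 and 4 adjusted over the list alone, list adjusted p = 0.49, 0.55 with an estimated correlation, and 0.040 in fry). Beside Slc26a4 the sodium-glucose transporter gene Slc5a1 rose by 3.94 ± 0.26, possibly a lower bound, from a low wild-type mean of 4.60, and the water channel gene Aqp4 fell by 1.24 (SE 0.13). Of these 3 rose without either transgenic replicate, and 5 fell without wild-type replicate 1 or 2. Adenosine pathway genes had 1 of 11 higher, 1 lower and 9 not passed (1 and 1 adjusted over the list alone, list adjusted p = 0.91, and 0.92 with an estimated correlation), namely the receptor gene Adora3 (0.52 ± 0.12) and Nt5e, which makes adenosine (-0.59 ± 0.13). Interferon-stimulated genes had 1 of 35 higher, Oas1a (1.49 ± 0.19), 2 lower, among them Ifit2 (-0.89 ± 0.11), and 32 not passed (1 and 2 adjusted over the list alone, list adjusted p = 0.68, and 0.92 with an estimated correlation). Adora3 lost its call without transgenic replicate 1 (adjusted p = 0.098) or 2 (0.13) or wild-type replicate 1 (0.052), and Nt5e without transgenic replicate 1 (0.15). The adenosine list turned higher without transgenic replicate 2 or wild-type replicate 1 (medians 0.00797 and 0.02), and in it 0 genes rose without either transgenic replicate or wild-type replicate 1, and 0 fell without transgenic replicate 1. The interferon list, whose mean was 8.30 in wild-type replicate 2 and 7.68 to 7.98 in the other wild-type arrays, leaned higher without wild-type replicate 2, when 4 genes rose. Without either transgenic replicate 1 interferon gene fell.

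Clock genes, which track the time of collection, fell in part, and genes that track its manner did not pass as a list. Of 18 circadian clock genes 2 rose, 9 fell and 7 did not pass (2 and 10 adjusted over the list alone, list adjusted p = 0.0049, and adjusted p = 0.10 with an estimated correlation). The repressor gene Bhlhe40 rose by 1.78 ± 0.28 and the period gene Per1 fell by 1.19 (SE 0.17), and 3 genes fell without transgenic replicate 1. Immediate early and heat shock genes did not pass (list adjusted p = 0.11, and 0.62 with an estimated correlation), with 1 of 26 higher, 6 lower and 19 not passed (1 and 7 adjusted over the list alone). Egr2 rose by 1.96 ± 0.52 and the phosphatase gene Dusp1 fell by 1.60 (SE 0.39). The mean of this list was 10.56 in wild-type replicate 3 and 9.17 to 9.47 in the other wild-type arrays, the list passed without wild-type replicate 4 (adjusted p = 0.024), and 1 gene fell without either transgenic replicate. The 1 rise was 3 without wild-type replicate 2 and 2 without wild-type replicate 3. Egr2 lost its call without transgenic replicate 1 (adjusted p = 0.15) or 2 (0.16) or wild-type replicate 1 (0.076) or 4 (0.052), and Dusp1 without transgenic replicate 1 (0.12) or 2 (0.15) or wild-type replicate 1 (0.063).

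Sex and strain genes did not pass. None of the 4 measured genes of either list passed in limma (0 adjusted over the list alone), and these lists were too small for the list test. Xist, expressed from the inactive X chromosome of females, lay between 11.71 and 12.17 in the 6 arrays (difference 0.29 ± 0.12, adjusted p = 0.13), and Mmrn1 differed by -0.39 ± 0.20 (adjusted p = 0.22). For both genes the transgenic values lay outside the wild-type range.

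The authors' deposited table of probe set comparisons gave the same log2 fold changes as the differences of means here, to within 1.7e-06. Among its probe sets, 846 had a q-value under 0.05, 514 of them higher and 332 lower in transgenic lungs, and 261 of them changed at least 2-fold. Tested probe set by probe set in limma, 5125 passed, 716 of which were among those 846. Of the largest rises, the q-value in the authors' deposited table was 0.062 for Mmp12, 0.20 for Arg1 and 0.18 for Chil4, and it was 0.14 for Bpifa1. Across probe sets, which are not independent, the authors' q-values ranked more closely with p-values that let each group have its own variance (Spearman's rho 0.991) than with those of limma (0.884).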

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

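The tests of mixed RNA, of airway epithelium as the whole cause, of varying heart and fat tissue and of a genotype difference in those genes were chosen after the results were seen.

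Among the 4 wild-type arrays, 11 of 167 values, of 9 genes and 2 lists, had 1 array far from the others by Dixon's test, where chance gives about 1 in 20. Wild-type replicate 2 was high for Slc26a4 (7.07 on the log2 scale, 5.39 to 5.59 in the others), Tff2 (9.52, others 7.796 to 7.92), Retnla (13.7, others 10.5 to 10.7), the mean of alternatively activated macrophage genes (8.23, others 7.97 to 8.01) and that of T cell and Th2 markers (5.47, others 5.33 to 5.34). Wild-type replicate 3 was high for Ccl3 (4.63, others 3.49 to 3.67) and Egr2 (7.79, others 5.75 to 6.00), and low for Csf2rb (8.03, others 8.22 to 8.25). Wild-type replicate 4 was high for Il13ra1 (7.42, others 7.02 to 7.08) and low for Tek (10.8, others 11.20 to 11.24), and wild-type replicate 1 was low for Fscn1 (6.09, others 7.29 to 7.42). Among 10092 probe sets without a single gene symbol, outside the comparison of genes, 544 passed in limma, the largest rise being 4.37 and the largest fall -3.82.

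Clca1, Retnla and Pigr were higher in wild-type replicate 2 than the mean of the other wild-type arrays by 5.52, 3.14 and 1.86 on the log2 scale. RNA of a transgenic lung mixed into this sample is argued against, since the 12 genes with the largest rise implied a median share of 0.354% and at most 2.46%, while Clca1 would need 99.0%. These 12 genes were chosen with transgenic values above every wild-type value, replicate 2 included, which favours a low share. Mixed RNA would nevertheless raise all of them. More airway epithelium in the sampled piece may contribute, as 55 of 59 club and ciliated cell markers were higher. The median over all 59 was 0.68, with 0.36 for club and 0.77 for ciliated cell markers, so the excess was mostly in ciliated markers. As the whole cause it is left open, since 3 of 3 genes lay above the highest of those markers (1.77) but were chosen for being high, Pigr by only 0.09, and Slc26a4 (1.57) and Tff2 (1.68) lay below it. A raised goblet cell programme in that animal stays open as a hypothesis. The 21 goblet genes left without Clca1, Pigr and Slc26a4 were at a median of 0.17, above 99.85% of 10000 matched random lists.

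The mean of cardiac muscle genes was lower in transgenic lungs by 1.26 on the log2 scale and that of adipose genes by 1.64. Varying amounts of heart and fat tissue in the samples are consistent with the spread, because the larger range within a genotype was 1.02 times the group difference for cardiac genes and 1.18 times for adipose genes. A difference between the genotypes cannot be told apart from this, since 4 of 4 pairs of transgenic array and list lay below all wild-type arrays, which for a single list chance gives in 6.67% of splits of 6 arrays.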

How the results depend on the processing

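The tests without both wild-type replicates 2 and 4 were chosen after the results were seen. Of the results of single genes under all alternatives 2107 kept direction and side of the threshold, 155 lost their call, 2 gained 1 and 5 reversed, and of those of lists 736, 59, 17 and 21. With every probe set tested on its own 2426 probe sets, not genes, were higher, 914 of them at least 2-fold, and 543 were at least 2-fold lower. The naming rule took 63 genes past the threshold that had several probe sets. For 31 of these every probe set passed in the same direction, and for the rest at least 1 did not. Among the rest were Ighm (5 of 11 passed), Trem2 (1 of 2) and Aqp4 (1 of 3). Genes higher numbered 835 without variance moderation (4 degrees of freedom alone), and 731 to 1578 leaving out 1 array. Genes lower numbered 693 without moderation and 580 to 2016 leaving out 1 array. At least 2-fold higher were 355 among genes at or above the median expression (fewer genes tested). At least 2-fold lower were 223 with the mean of a gene's probe sets and 153 without moderation. Calls of single genes in this text ended in 39 cases without moderation. With an intensity trend and robust moderation 12 ended, and with every probe set tested on its own 7. With an estimated correlation 3 lists were higher and 0 lower, and fry called 6 lower. Replicate numbers as a block gave 1609 higher and 2150 lower genes. This fit compared the transgenic arrays with wild-type replicates 1 and 2 only, as wild-type replicates 3 and 4 have no transgenic partner. With fewer residual degrees of freedom than the main fit, it is no check of pairing across all arrays. Deviations of equally numbered arrays correlated at -0.076 and 0.274 across genes, which does not settle whether the numbers mark a pairing. Under this block Muc5ac was at -0.31, the collagen and extracellular matrix list at 0.22 and basal cell markers at 0.13. Within lists, 9 cardiac and 5 adipose genes fell, but 3 and 2 with an intensity trend and robust moderation, and 17 and 8 with the block, under which 25 ciliated cell markers fell in place of 4. Wild-type replicate 2, 1 of the 2 controls under the block, had the highest ciliated mean (7.14, other wild-type arrays 6.24 to 6.47). For Muc5ac it lay 1.02 above the mean of the other wild-type arrays. Shifts under the block cannot be read as effects of pairing, since the controls compared also changed. Lists whose test direction reversed, each without a call in that setting, gave these medians. Inflammatory (classical) macrophage genes were at -0.29 among genes at or above the median expression, where collagen and extracellular matrix genes, not called in the main analysis, were at -0.25. The collagen and extracellular matrix list was at -0.13 with a log2 value of at least 6 in 2 arrays, 0.03 (0.0253) with the mean of probe sets, -0.03 (-0.0256) with the most variable probe set, 0.03 (0.0347) in fry and -0.15 to 0.18 leaving out 1 array. Adenosine pathway genes were at 0.00908 with the mean of probe sets and with the most variable one, and -0.11 to 0.0232 leaving out 1 array. Interferon-stimulated genes were at 0.0195 without both wild-type replicates 2 and 4 and -0.25 to -0.0424 leaving out 1 array. Basal cell markers were at 0.17 with the most variable probe set, 0.0683 without both wild-type replicates 2 and 4, and -0.10 to 0.10 leaving out 1 array. Leaving out 1 array put Muc5ac at -0.11 to 0.29 and Sftpc at -0.0195 to 0.0688. Where no reason is given, the cause was not tested. Genes near the floor of the arrays, such as Il13 and Epx, are limited by signal over background.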

Other observations

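The tests of gene families and of dilution were chosen after the results were seen.

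Families of genes with a shared symbol stem were tested in limma's camera at the preset correlation, 296 of them with at least 8 genes, and 9 were higher and 5 lower in transgenic lungs. With an estimated correlation 0 passed, the lowest adjusted p being 0.657, so these are descriptions of the genes. Of 8 Csf genes, colony stimulating factors and their receptors, 5 rose, with the receptor subunits Csf2rb2 at 3.01, Csf2rb at 2.82 and Csf2ra at 2.03 on the log2 scale. Of 11 Tlr genes, receptors for microbial products, 7 rose, led by Tlr13 (2.49) and Tlr7 (2.22). Of 336 Zfp genes, mostly zinc finger transcription factors, 3 rose and 62 fell, with a median of -0.29, and of 16 Klf genes 6 fell. Of 22 genes of the V-ATPase, the proton pump of lysosomes, 16 rose and 1 fell, with a median of 0.65, and no test of them as a group was run. Among the risen were Atp6v0d2 (3.32), Atp6v1b2 (1.76) and Atp6v1c1 (1.30). The genes of this paragraph other than Atp6v0d2 were chosen after their values were seen.

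Many endothelial and alveolar type I markers were lower while most type II markers were not. Dilution of all lung cells alike by added immune cells, as the only change, would lower the endothelial and type II lists equally. The median of type II markers exceeded that of endothelial markers by 1.15 on the log2 scale (bootstrap 95% interval 0.857 to 1.66). The interval resamples genes and not animals, so it leaves out the spread among animals. Without genes whose mean reached 13 in either genotype, a limit chosen after the results were seen, 13 of 24 type II and 35 of 36 endothelial markers were left. Among these the excess was 0.986. This argues against such dilution only as far as added immune cells do not express genes of the type II list. Lyz2 stands on both that list and the list of monocyte and interstitial macrophage markers. Of 10000 random lists matched on expression, 0% had a median as low as the endothelial markers. This argues only against a bias of normalization that genes of like expression share, and other effects of normalization were not tested. The comparison largely repeats the list test, and random lists lack the correlation of 0.28 estimated for the endothelial markers. The median of 9 surfactant and lamellar body genes, chosen after the results were seen, was 0.05, so a rise of genes within type II cells that offsets dilution was not separated from this. Sftpc, 1 of the 9, was near saturation, where a change would be compressed, so a small median does not show an unchanged level. Fewer endothelial cells and less RNA of these genes per cell both stay open.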
